A study of Drosophila melanogaster with 4 samples.

How the data were processed

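The series profiled binding of Hairy by chromatin immunoprecipitation and sequencing (ChIP-seq) in Kc167 cells, a female, embryo-derived Drosophila melanogaster line. The labels describe 4 libraries: 3 immunoprecipitated with the rabbit polyclonal antibody KW3-h-D1 against Hairy, and 1 input library of unenriched chromatin. Per the labels' protocols, the cells were crosslinked with formaldehyde and the chromatin was sonicated. Nothing in the labels says whether the 3 ChIP libraries came from separate cultures.

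The data analysed were 1 deposited list of peaks for the whole series. Per the file headers, peaks were called with MACS and coordinates are on FlyBase release 5. The submitters' processing notes name CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5, with no roles or settings. The calling threshold, the use of the input and the treatment of the 3 ChIP libraries (pooled or called singly) are not given in the sources used here. The list has 1 start, 1 end and 1 score per peak and no value per library, so no statement below carries an error between replicates. Read totals per library were not analysed here, and the depth is unknown.

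The deposited score is not named in the list, and its statistic was worked out from its values. Common scores form a ladder whose steps grow with the score. The 44 scores from 10 to 20 that occur at least 25 times were matched to successive whole numbers of fragments k, taking the score as −log10 of the Poisson probability of more than k fragments over 1 constant background. The background was set to the value, in steps of 0.001, that placed most peaks within 0.006 of the ladder. It came to 157.836 fragments, with a largest error of 0.00557 over the 44 scores and 0.00758 over the 93 common scores up to 30. Evenly spaced steps, as a fold enrichment would give, missed the same 44 scores by up to 0.240. The score is therefore treated as the authors' −log10 p-value, and it is used within this list only: to rank peaks, to compare sets of peaks on the log2 scale, and to recover the fold. A peak was taken to lie on the constant background if its score was within 0.01 of the ladder. This held for 9749 of 13577 peaks (71.8%), against 12.5% expected for scores falling at random between the steps. The same background fitted peaks of very unlike width (534 and 7079 bp among the 20 highest scores). The recovered count k is therefore not the number of fragments over a whole peak, and the fold is not that of a whole peak. Which part of a peak it refers to is not given. MACS uses a higher local background where it finds one, so for the remaining 3828 peaks the recovered fold is a lower limit of the fold over the constant background and an upper limit of the fold over their own background. Because the use of the input is not given, it is unknown whether the local background was taken from the ChIP or the input libraries. Intervals on a fold are exact 95% Poisson intervals of the fragment count; fragments amplified by PCR are not independent, so they cover counting error only.

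Peak positions were midpoints. Arms were taken from position 1 to the end of their last peak, because no release 5 sequence was used. The number of peaks per 100 kb bin was compared between X and the 4 autosomal arms 2L, 2R, 3L and 3R by a two-sided permutation test with 100000 resamples of bins. Pairs of arms were compared in the same way, with Benjamini-Hochberg adjustment over the 10 pairs. Neighbouring bins resemble each other, so these p-values are too small, and bins of 500 kb and 1 Mb were also used. The median distance between neighbouring peaks was compared with 1000 uniform placements of the same number of peaks on each arm, by a one-sided permutation test. The results were recomputed for the 50% and the 25% of peaks with the highest scores, with bins of 500 kb, without empty bins, and with peaks within 500 bp merged. The test of X against the autosomes, the spacing test, these settings, the gene and motif lists and the rule for named items were fixed before the data were examined. The pairs of arms, bins of 1 Mb, gaps of 1000 and 5000 bp for joining peaks and the reading of the score were added after. The rule named the 20 peaks with the highest score, by coordinates where no annotation of the build was used.

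Of the planned results, 6 were not run: peaks at promoters, annotation classes, score by class, motif sites, motif share by score, and the 20 gene lists. They need the release 5 sequence and annotation; the gene table at hand is on release 6, and coordinates of different builds were not combined. No peak is therefore assigned to a gene. The comparisons of heterochromatic and unplaced sequences, of centromere-proximal ends, and of background with density were added after seeing the data.

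The score fit, the test of X against the autosomes and the spacing test were tested on simulated data. With 13577 simulated peaks and known backgrounds, the background was recovered to within 0.001 fragments, and at most 14.5% of peaks with a local background were taken for constant. In 100 simulations of X against the autosomes over 1187 bins, the permutation test called 4% with no difference and 100% with a 1.5-fold difference. The simulated bins were independent, while real neighbouring bins were correlated, from 0.12 on 3R to 0.51 on 3L among the large arms. These rates therefore do not cover that dependence. With 13319 simulated positions, 30.5% of 200 uniform placements had a median distance at or below that of uniform positions, and 0% at or below that of positions in pairs 500 bp apart. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.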

Results

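Hairy is a basic helix-loop-helix transcriptional repressor, known for its role as a pair-rule gene product in embryonic segmentation. Its binding was profiled in Kc167 cells with 3 ChIP libraries and 1 input library, and the question addressed was where on the genome Hairy binds in these cells. The result is a single list of 13577 peaks, which together covered 9939366 bp. Because the list holds no value per library, no comparison could be set against the spread between the 3 ChIP libraries.

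Most Hairy peaks were narrow as called and rose modestly above background. Many lay close together: joined over gaps of at most 500 bp, they formed 7699 regions. A called width is therefore not always that of a whole enriched region. The median peak was 478 bp wide (quartiles 302 and 871 bp), and the widest spanned 9905 bp. The median score, read as −log10 of the authors' p-value, was 15.48 (quartiles 11.28 and 24.1), and scores ran from 5.92 to 653.65. For the 9749 peaks on the constant background of 157.836 fragments, the median recovered count was 268 fragments. This is 1.698-fold over background, and the quartiles of these peaks were 1.58 and 1.90-fold. A single peak with that count has a counting interval of 1.501 to 1.914-fold, which does not measure the uncertainty of the median. Over all 13577 peaks, 2566 (18.9%) reached a fold of 2 over the constant background, 161 (1.19%) a fold of 3 and 39 (0.287%) a fold of 4. Because some peaks had a higher local background, these counts are lower limits for the fold over the constant background and upper limits for the fold over each peak's own background. Wider peaks had higher scores across peaks (Spearman rho = 0.74 and Pearson r = 0.74 on log2 values, permutation p = 0.001 for each, the smallest that 1000 permutations can give). Peaks are not independent replicates. Width and score also come from the same called signal, so peak calling sets part of this relation, which the permutation test does not allow for. The lowest 25% by score had a median width of 281 bp and the highest 25% of 1216 bp. No peak was shorter than 201 bp and no 2 peaks lay closer than 50 bp, so both widths and spacings have a floor.

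**Figure D1:**
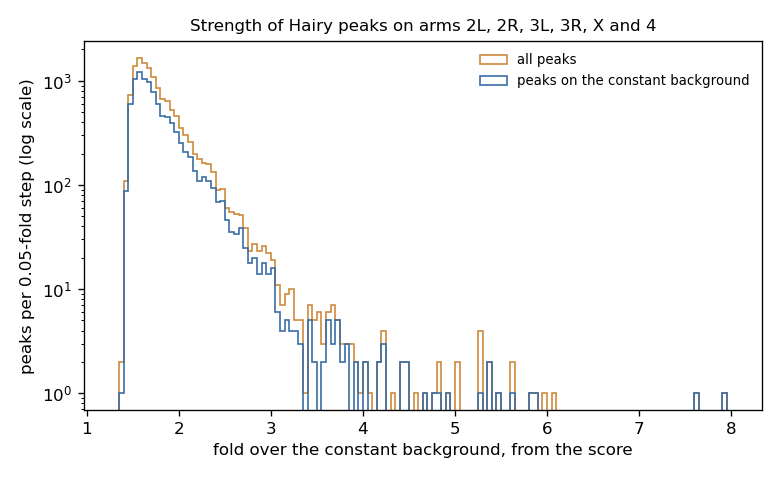
Histogram of peak strength for peaks on 2L, 2R, 3L, 3R, X and 4, with fold over the constant background on the x axis and the number of peaks per 0.05-fold step on a log y axis; the orange line is all peaks and the blue line those on the constant background. Most peaks lie below 2-fold and the strongest reaches 7.93-fold.

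A small number of sites stood far above the rest. The strongest Hairy peak lay on 2R from 17589851 to 17592556 (release 5), with a score of 653.65. Its recovered count was 1252 fragments, 7.93-fold over background (counting interval 7.50 to 8.38). The next was on 3R from 25541453 to 25544436, at 7.65-fold (interval 7.22 to 8.09). Both lay on the constant background. The interval of the strongest X peak, from 13277181 to 13278926, was 5.51 to 6.28-fold around 5.89, below both of these. The next peaks by score outside X were on 2L from 18706668 to 18710317 (score 405.17), on 2R from 16771617 to 16772352 (score 396.77), and on 3L from 18107212 to 18108498 (score 378.2). Those on 2L and 2R lay off the constant background, and that on 3L lay on it. The 20 highest-scoring peaks fell on 3R (7 peaks), X (4), 2R (3), 3L (3), the small chromosome 4 (2) and 2L (1). The pair on chromosome 4, from 424407 to 426356 and from 445026 to 445721, had scores of 353.13 and 310.33. Both lay off the constant background, as did 59.1% of the 137 peaks on that chromosome. Some other peaks among the 20 lay off it too.

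Some of the 20 highest-scoring peaks lay on the same part of an arm, which was not tested against random positions. On 3R, a 7079 bp peak from 21829700 to 21836778 (score 321.98) was followed by one from 21845298 to 21848124 (score 311.91). On 3L, the peak from 18012364 to 18013671 (score 335.22) lay upstream in coordinate of that at 18107212. This pair lay much farther apart than the pair on 3R. The other peaks of the 20 scored between 260.38 and 348.62.

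Hairy peaks were strongly clustered along the chromosomes. On 2L, 2R, 3L, 3R, X and 4, the median distance between the midpoints of neighbouring peaks was 1559 bp, against 6090 bp for uniform placements of as many peaks (range over 1000 placements 5903 to 6278 bp). The observed distance was 0.256 of the uniform one (one-sided permutation p = 0.001, from random placements, the smallest that 1000 placements can give). Among the 25% of peaks with the highest scores, it was 7570 bp against 24542 bp. When peaks at most 500 bp apart were joined, 7699 regions remained, and those on the 6 sequences above were still spaced at 4328 bp against 10920.5 bp. Of the 7699 regions, 4758 (61.8%) held a single peak.

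How many dense regions there were depended on the gap over which peaks were joined. At the 500 bp gap, 15 regions held at least 10 peaks each (167 peaks together, at most 15 in a region); at 1000 bp there were 121 such regions (1588 peaks), and at 5000 bp 404 (7319 peaks). At 5000 bp, the region with the most peaks was on 2R from 9781904 to 9900081, with 73 peaks. At 1000 bp, it was on 3R from 12032115 to 12091995, where 31 peaks covered 49466 bp of 59881 bp (82.6%) and reached a score of 233.39. The next by number of peaks at the 1000 bp gap were also on 3R: the region from 23754628 to 23784403 held 25 peaks, that from 23077334 to 23119159 held 24 peaks and that from 13516149 to 13543909 held 23 peaks. On 3L, 22 peaks lay between 3422721 and 3461717 and 21 peaks between 8668309 and 8703135. On 2L, 22 peaks lay between 18685633 and 18711841, a region that contains the strongest peak of that arm, and a further 20 peaks between 476650 and 507493. On X, 20 peaks lay between 18521062 and 18554019, and on 2R 20 peaks between 3402040 and 3427816.

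Other parts of the arms held few peaks or none. The 119 densest of the 1187 bins of 100 kb on the 5 large arms held 4485 of 13182 peaks (34.0%). In contrast, 206 bins (17.4%) held no peak, where 0.0859 empty bins would be expected if peaks were spread evenly along each arm. There were 24 intervals of at least 300 kb between neighbouring peaks, of which 9 were on 3L, 8 on 2L, 5 on X, 1 on 2R and 1 on 3R. The longest, on 2L from 8614244 to 9697350, was 1083 kb long, and the next, also on 2L from 3650704 to 4332738, was 682 kb. The longest interval in any of 1000 uniform placements was 204 kb. Missing sequence and sequence to which reads cannot be placed would also appear as empty, and were not analysed here.

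The arms differed in how many peaks were called on them. DNA copy number and read depth along the arms were not measured, and both can change how many peaks are called. The differences below are therefore in called peaks, and are not shown to be differences in Hairy binding. Per 100 kb bin, 2R had 13.9 ± 12.1 peaks (SD over 209 bins), 3R 12.5 ± 12.6 (279 bins), X 11.8 ± 12.2 (222 bins), 2L 9.30 ± 11.7 (231 bins) and 3L 8.29 ± 10.4 (246 bins). Chromosome 4 had 10.5 ± 4.37 peaks over 13 bins. Peaks covered 10.1% of the span of 2R and 5.77% of that of 3L. Arm 3L had fewer peaks than 2R (ratio of 2R to 3L 1.67, adjusted p = 0.0001, permutation test), fewer than 3R (ratio of 3L to 3R 0.664, adjusted p = 0.00023) and fewer than X (ratio of 3L to X 0.703, adjusted p = 0.0022). Arm 2L had fewer than 2R (ratio 0.671, adjusted p = 0.00023), 3R (ratio 0.745, adjusted p = 0.0073) and X (ratio 0.789, adjusted p = 0.045) by the same permutation test. In bins of 1 Mb, the differences of 2L from 2R, of 3L from 2R and of 3L from 3R were again past the threshold (permutation test, adjusted p = 0.034 for each), and those of 2L from 3R, 2L from X and 3L from X did not (adjusted p = 0.078, 0.24 and 0.15). Both arms had long segments with low mean counts: 370 peaks on 2L from 2 to 10 Mb (46.2 per Mb) and 490 peaks on 3L from 6 to 18 Mb (40.8 per Mb), where a lower share of peaks lay off the constant background than in the other segments of these arms. These segments were not evenly sparse: 85 of the 370 peaks lay on 2L from 8 to 8.5 Mb, and 53 of the 490 on 3L from 8.5 to 9 Mb.

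**Figure D2:**
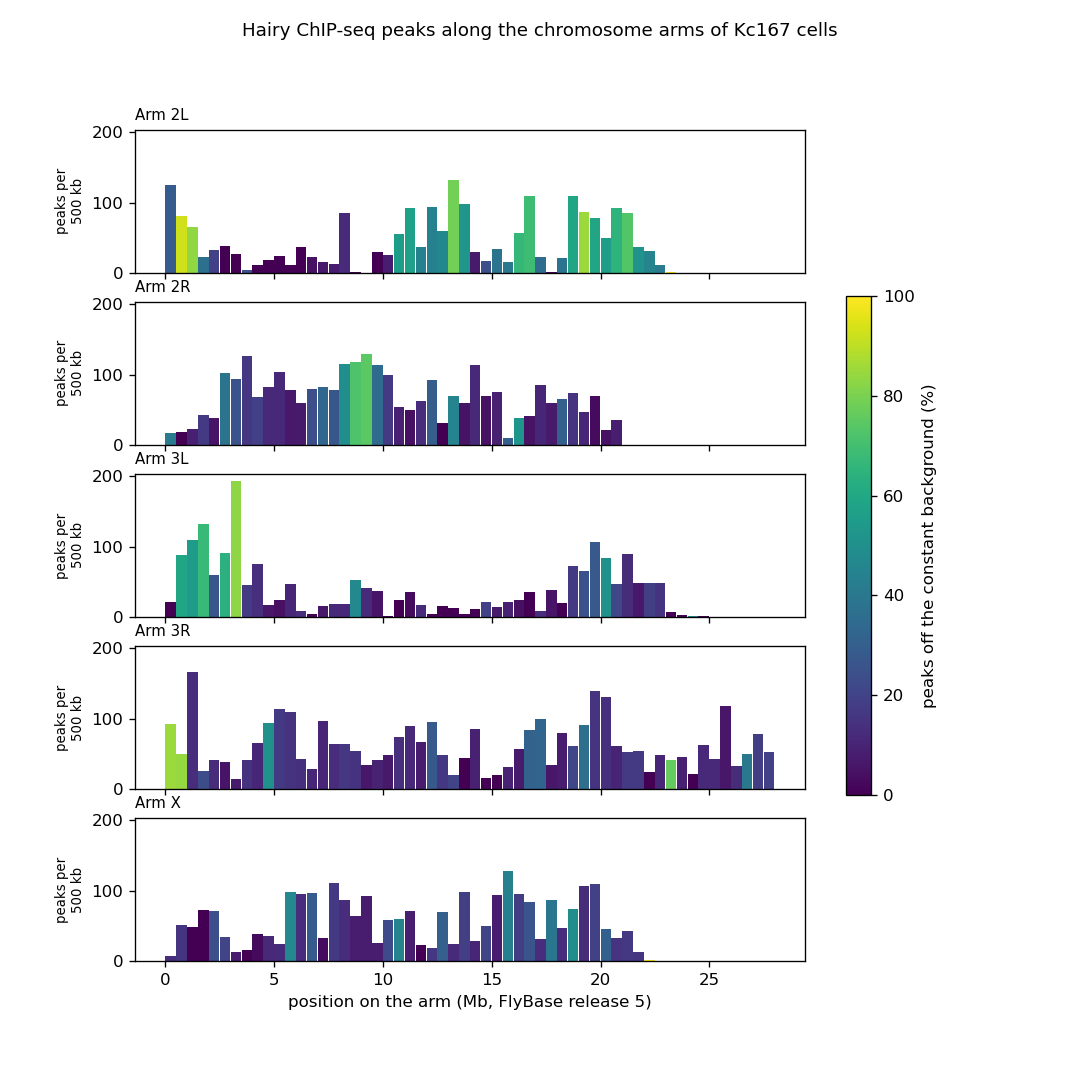
Number of Hairy peaks per 500 kb bin (y axis) against position in Mb on FlyBase release 5 (x axis) for the 5 large arms; each bar is 1 bin and its colour gives the percent of its peaks off the constant background. Most bins hold few peaks on 2L from 2 to 10 Mb and on 3L from 6 to 18 Mb, where 5.41% and 10.6% of peaks lie off the constant background; the bins from 8 to 8.5 Mb on 2L (85 peaks) and from 8.5 to 9 Mb on 3L (53 peaks) hold the most in these segments.

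No difference in peak density was detected between the X chromosome and the autosomal arms as a whole. The X carried 11.8 peaks per 100 kb bin and the autosomal arms 10.9 ± 11.9 over 965 bins, a ratio of 1.08 (two-sided permutation p = 0.35). In bins of 500 kb, the ratio was 1.07 with a 95% bootstrap interval of 0.877 to 1.29. The ratio was 1.04 for the 25% of peaks with the highest scores (permutation p = 0.66). Among peaks on the constant background alone, X had 9.44 peaks per bin and the autosomes 7.79, a ratio of 1.21 (permutation p = 0.013). The share of peaks off that background was 19.9% on X, 19.1% on 3R, 23.6% on 2R, 32.0% on 3L and 48.6% on 2L. The rise from 1.08 to 1.21 comes from leaving these peaks out, and is not evidence of denser binding on X.

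Peaks on sequence outside the main arms were few and had higher scores. The unplaced sequence Uextra held 178 peaks, U held 16, and the heterochromatic sequences 3LHet, 2RHet, 3RHet and 2LHet held 32, 16, 11 and 5. These 258 peaks had a median score of 24.7, against 15.32 for the 13182 peaks on the 5 large arms. Their mean log2 score was higher by 0.54 (two-sided permutation p = 0.0001, the smallest that 10000 resamples can give). Single peaks were permuted in this test, and peaks cluster, so this p-value is too small. The 258 peaks were narrower, with a median of 352 bp against 481 bp. Of them, 69.4% lay off the constant background, against 27.1% on the arms. Both values rest largely on Uextra, with a median width of 345.5 bp and 75.8% off that background. The shares were 75% on U, 65.6% on 3LHet, 43.8% on 2RHet, 27.3% on 3RHet and 20% on 2LHet. Median widths were 290 bp on U, 346 bp on 3RHet and 417 bp on 3LHet. They were above that of the arms on 2RHet (527.5 bp) and 2LHet (760 bp).

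The centromere-proximal ends of 2R and 3L held a few strong peaks. In the proximal 1.5 Mb of the span covered by peaks, 59 peaks on 2R had a median score of 33.69, against 15.24 on the rest of that arm. On 3L, 14 proximal peaks had a median score of 48.84, against 15.01. Compared as means per 100 kb bin, the log2 score was higher by 1.26 on 2R and by 1.21 on 3L (adjusted p = 0.00025 for each, permutation test, over 5 arms). On 2L, 3R and X, the difference was between 0.12 and 0.13, with an adjusted p of 0.42 for each.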

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

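Bins of 1 Mb, joining gaps of 1000 and 5000 bp, segments without their densest bin, peaks on the constant background, each arm left out, and the settings for the background and the proximal ends were chosen after seeing the data. The ratio of X to autosomal peak density kept its direction and stayed short of the threshold in the 4 settings fixed beforehand (1.04 to 1.07) and in bins of 1 Mb (1.06). Without 3L it was 0.99 (permutation p = 0.94), and the sign then turned because 3L has the fewest peaks per bin; without 2R it was 1.16 (p = 0.069). It passed the threshold among peaks on the constant background (1.21). That set leaves out a larger share of the peaks on 2L (48.6%), 3L (32.0%) and 2R (23.6%) than on X (19.9%), against 19.1% on 3R. The rise in the ratio follows from these shares, and why they differ was not tested. The spacing ratio stayed below uniform in the 3 settings tried, from 0.256 to 0.396. The top 50% by score held 6866 peaks (median width 826 bp, median score 24.1) and the top 25% held 3443 (1216 bp and 34.6); the selection by score sets their number and raises the score, and the greater width goes with the correlation of width and score (rho = 0.74). The number of regions with at least 10 peaks moved from 121 at a gap of 1000 bp to 15 at 500 bp and 404 at 5000 bp. The share of peaks on the constant background was 69.1% within 0.006 and 74.5% within 0.02. The score difference of the proximal ends, 0.52 on the log2 scale, was 0.30 to 0.53 for ends of 1 to 3 Mb, and 0.12 (permutation p = 0.13) without 2R and 3L. No paired analysis was possible because the list has no value per library; for the same reason no replicate could be left out. Alternatives for promoters, annotation classes, motifs and gene lists were not run. Depth is unknown, so the limit it sets on weak peaks was not assessed.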

Other observations

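The tests of background and of heterochromatic and unplaced sequence in this part were chosen after the result was seen; the test on merged peaks was planned. Long stretches of 2L and 3L differed in both peak number and background. On 2L, the segment from 2 to 10 Mb held 46.2 peaks per Mb, of which 5.41% lay off the constant background, while that from 0 to 2 Mb held 147 per Mb with 59.2% off it and that from 10 to 23 Mb held 114 per Mb with 57.3% off it. On 3L, the segment from 6 to 18 Mb held 40.8 peaks per Mb with 10.6% off the constant background, and that from 0 to 6 Mb held 151 per Mb with 50.9% off it. The segment of 3L from 18 to 24 Mb was dense, at 106.5 peaks per Mb, with a lower share of 21.8% off the constant background. Single bins weighed on these values: 25 of the 52 peaks off the constant background on 3L from 6 to 18 Mb lay in the bin from 8.5 to 9 Mb (47.2% of its 53 peaks). Without the densest 500 kb bin of each, the segment of 3L held 38 peaks per Mb with 6.18% off the constant background, and that of 2L from 2 to 10 Mb held 38 per Mb with 3.51% off it. The 25% of peaks with the highest scores were also fewer per Mb in these 2 segments, at 6.75 per Mb on 2L from 2 to 10 Mb and 7.75 on 3L from 6 to 18 Mb. They numbered 35.6 per Mb on 2L from 10 to 23 Mb, and 41.3 and 23.8 per Mb on 3L from 0 to 6 and from 18 to 24 Mb. Because the score rises with the number of fragments, a segment with fewer reads would lose such peaks too, so this is no separate evidence of less binding. These segments were chosen from the data and were not tested against each other.

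Across 223 bins of 500 kb with at least 10 peaks, the number of peaks rose with the share of peaks off the constant background (Spearman rho = 0.49, Pearson r = 0.44, permutation p = 0.0001 for each; r = 0.44 without the 2 bins farthest from the median share). Spearman's coefficient was positive in each of the 5 arms, from 0.39 on 3R to 0.78 on 3L (highest adjusted p = 0.0049), while Pearson's r on 3R was 0.18 (permutation p = 0.2). Neighbouring bins are not independent, so these p-values are too small. Over the 5 arms, Spearman's coefficient was 0.54 in bins of 1 Mb and 0.50 in bins with at least 5 peaks. It was lower, at 0.30, in bins of 100 kb with at least 10 peaks. Whether the local background was taken from the ChIP libraries or the input is not known. If it came from the ChIP libraries, signal of called peaks within 5 kb as the whole source of the raised background is argued against. If it came from the input, ChIP signal does not enter it and the comparison below does not bear on this source. Among sparse peaks, those with the least such signal, 33.2% lay off the constant background where signal 5 to 50 kb away was greatest. Where that signal was least, 11.1% did, a ratio of 2.98 (Fisher's exact p = 3.4e-20). Peaks cluster, so this p-value is too small. Enrichment below the calling threshold within 5 kb, and differences in signal among the sparse peaks, were not controlled. A background raised over whole segments is a candidate explanation, since these sparse peaks followed the other peaks of their bin (rho = 0.48 over 198 bins); it may reflect DNA copy number in this line or broad differences in chromatin, which these data cannot separate, and no biological explanation was tested.

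The clustering of peaks might come from broad bound regions that the peak caller split into several. For splits over gaps of at most 500 bp, this is argued against as the whole cause. Regions joined over 500 bp were still spaced at 0.396 of the uniform distance. Splits over wider gaps stay open, because regions joined over wider gaps were not compared with uniform placements. A partial contribution of splitting was not tested. Gene density along the arms was not used here and stays open.

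The higher scores on heterochromatic and unplaced sequence were also seen among peaks on the constant background, where the log2 score was higher by 0.77 than on the arms (79 against 9614 peaks, two-sided permutation p = 0.0001), against 0.54 over all peaks. About 22.0 of the 79 would be expected there by chance. Peaks are not independent, so the p-value is too small. Pooled over these sequences, the share of peaks off the constant background was 2.56 times that on the arms. Of the 179 such peaks, 135 were on Uextra. No explanation of these scores was tested.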
